A study of Mus musculus with 12 samples.

How the data were processed

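The series holds 12 one-colour Illumina bead arrays of newborn C57BL/6 mouse tissue, 3 each of Krt1+/+ epidermis, Krt1-/- epidermis, Krt1+/+ full-thickness skin and Krt1-/- full-thickness skin. Per the labels' protocols, RNA was taken with Trizol and RNeasy columns and amplified to biotin-labelled cRNA with an Ambion MessageAmp kit. The non-normalized table deposited by the authors gives the mean bead intensity of each of 45281 probes on a linear scale, with background not subtracted and arrays not scaled to each other. The same table gives, per the file headers, a detection p-value for each probe and array. A second deposited table holds intensity values with the same ranks within each array (rank correlation 1) and the same median on every array, 99.2, so they were treated as quantile normalized; the method is not given in the sources used here. The scanner software and its settings are not given in the sources used here either. Groups were taken from the labels, which give genotype, tissue and a replicate number, and do not say that arrays of a group came from separate animals or that equal numbers pair samples.

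Intensities were background-corrected and quantile normalized over the 12 arrays with neqc of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values and an offset of 16, and then taken as log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays, which left 21712 probes. Gene symbols came from the platform annotation, brought to the current symbol of the mouse reference by gene ID for 34807 probes and by accession for 11, and kept as annotated for 67; 10 symbols changed. Of all probes 34885 had 1 symbol, 18 several and 10378 none. Of the kept probes 18687 had 1 gene and 3025 did not, and the latter were left out of the counts of genes. Each gene was read by its kept probe with the highest mean, giving 12099 genes, 4531 of them with over 1 probe. Median signals of 93.3 to 105.1 lie close to those of undetected probes, so changes of dim genes are compressed by the background. At the other end, Lor, Krt10, Krt14, Krt16, Krt17, Krt6b, Rptn, Sprr1b, Col1a1 and Myh8, of the genes named here, read on average at least 50% of the brightest probe of the array in a group, so their folds may be compressed too.

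A limma fit of the 4 groups (lmFit, contrasts.fit, eBayes; 8 residual and 5.39 prior degrees of freedom) gave Krt1-/- minus Krt1+/+ in epidermis and in skin, the difference of these effects (epidermis minus skin) and skin minus epidermis in Krt1+/+. Adjusted p is by Benjamini-Hochberg over the genes tested, and a gene passed when it was under 0.05. Folds are of background-corrected values; where a gene was undetected on all 3 arrays of a group, a lower bound is given with that group at its detection limit, and no fold is given for an average that includes such a group. Each of 33 fixed gene lists was tested with camera (inter-gene correlation preset at 0.01), adjusted over the lists of a contrast; most such calls end when the correlation is estimated from these arrays. The lists cover differentiation (early suprabasal, cornified envelope, small proline-rich, late cornified envelope, barrier lipid, cholesterol), basal layer, stress keratins, desmosomes, tight junctions, proteases and inhibitors, alarmins, cytokines, chemokines, inflammasome, interferon, oxidative stress, heat shock, immediate early genes, proliferation, extracellular matrix, and markers of 12 cell types or structures.

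The groups, contrasts, tests, thresholds, gene lists and the rule for naming genes were chosen before the data were examined. Named were, for each genotype contrast, the 10 largest rises and the 10 largest falls among genes that passed and whose arrays did not overlap between genotypes; Krt1; 15 fixed genes; and, from each list, members among the 4 with the smallest unadjusted p in that contrast. For the difference of effects and for skin against epidermis, the 5 largest in each direction were named. Genes with only a clone-type name were skipped. Krt2 and Flg, of the fixed genes, were not analysed here. The averages over both tissues and over both genotypes, and the inclusion of probes without 1 gene, were added after the data were seen; the same naming rule was applied to the average over both tissues, among genes whose arrays lay apart in the same direction in each tissue.

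Alternatives were no background correction, median centring in place of quantile normalization, quantile normalization within each tissue, the deposited normalized table, no detection filter, a stricter filter (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, each probe on its own, trended and robust variance, only the arrays of the comparison, a threshold of at least 1.5-fold, the replicate number as a block, each array left out in turn, camera with estimated correlation, and fry. Normalized gene values were simulated with the spread of these arrays and 50 changed genes per fold size, and given the same fit and camera test. Of genes with a 1.5-fold change 10% passed in epidermis, 62% at 2-fold, 94% at 4-fold and 98% at 8-fold. In skin the shares were 10%, 68%, 94% and 100%, for the average 36%, 88%, 98% and 100%, and for the difference of effects 4%, 24%, 88% and 90%. False calls were 5.71%, 5.56%, 5.85% and 4.63% of calls, and 0 of 50 random lists were called in each. The simulation did not repeat normalization, the detection filter or the choice of probes. It changed far fewer genes than passed in the data, and held no array-set difference between genotypes and no correlation between genes. It therefore does not check the preset correlation of camera.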

Results

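Gene expression was measured on 12 one-colour bead arrays in newborn mice (postnatal day 0) that carried keratin 1 (Krt1+/+) or lacked it (Krt1-/-). Keratin 1 is a keratin of the suprabasal, differentiating layers of the epidermis. The arrays fall into 4 groups of 3: Krt1+/+ epidermis, Krt1-/- epidermis, Krt1+/+ full-thickness skin and Krt1-/- full-thickness skin. The series compares the genotypes in each tissue. The median signal of an array lay between 93.3 and 105.1 intensity units, and between 17184 and 19931 of 45281 probes (37.9% to 44.0%) were detected above background. Arrays of the same group correlated at 0.966 to 0.986, and 0 pairs of arrays held identical values. The small number of arrays limits the precision of every value, and because the labels do not say that arrays of a group came from separate animals, p-values measure only the spread between these samples, which may be technical. Of the genes on the array, 12099 were tested. Adjusted p of a gene is limma's over these genes, and adjusted p of a gene list is camera's over 33 lists, both by Benjamini-Hochberg.

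Krt1 itself was read by probe ILMN_2651772 and was detected on all 12 arrays. Its normalized log2 intensity was 12.10 ± 0.78 (SD, n = 3) in Krt1+/+ skin and 7.40 ± 0.84 (SD, n = 3) in Krt1-/- skin. Krt1 thus fell by 4.70 on the log2 scale in Krt1-/- skin, which is 26.0-fold lower (95% confidence interval −5.96 to −3.44, adjusted p = 8.1e-05). In epidermis it was 11.33 ± 1.09 (SD, n = 3) on the Krt1+/+ arrays and 10.26 ± 0.86 (SD, n = 3) on the arrays labelled Krt1-/-. That change of −1.07 did not pass (95% confidence interval −2.33 to 0.19, adjusted p = 0.18). The raw signals on the arrays labelled Krt1-/- epidermis ran from 987 to 2921, within or below the 1417 to 5954 of Krt1+/+ epidermis and above the 183 to 319 of Krt1-/- skin. The genotype effect on Krt1 differed between the tissues (adjusted p = 0.0047). Whether the probe lies inside the deleted part of the gene is not given in the sources used here, so the probe checks the labels only as far as its signal falls. Every direction given for epidermis rests on the labels of those arrays.

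**Figure D1:**
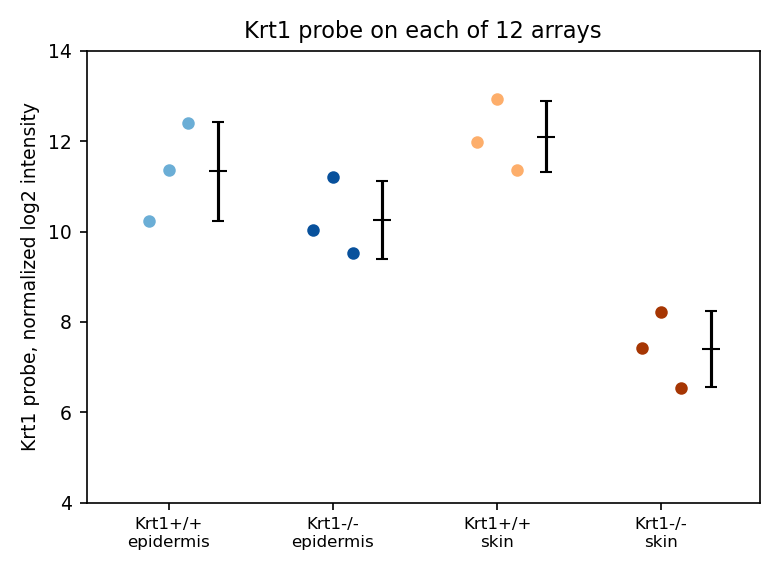
Normalized log2 intensity of the Krt1 probe on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars). The Krt1-/- skin arrays lie below all others, while the arrays labelled Krt1-/- epidermis (mean 10.26) overlap those of Krt1+/+ epidermis (mean 11.33).

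The arrays also separated in a way that follows neither tissue nor genotype. Over the 16240 probes that were undetected on every array, Krt1+/+ epidermis resembled Krt1-/- skin (mean correlation −0.0369) and Krt1-/- epidermis resembled Krt1+/+ skin (−0.0182), while pairs of groups across these 2 array sets correlated at −0.156 to −0.130. Krt1-/- skin replicate 1 is an exception and joins neither set. The split into these sets separated the undetected probes more strongly than any other of the 462 splits into 6 and 6 arrays, and the splits by tissue and by genotype ranked 257 and 389. One set also fills the first 6 sample columns of the deposited tables and the other the last 6. Within each tissue, genotype and array set cannot be told apart. A difference between the sets that adds to a probe's log2 value cancels in the average of both genotype contrasts, which equals a fit with the set as a block. This needs all arrays of a set to carry the difference alike, which is not shown for Krt1-/- skin replicate 1. That average was added after the data were seen, and is given below beside the contrasts of single tissues.

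**Figure D2:**
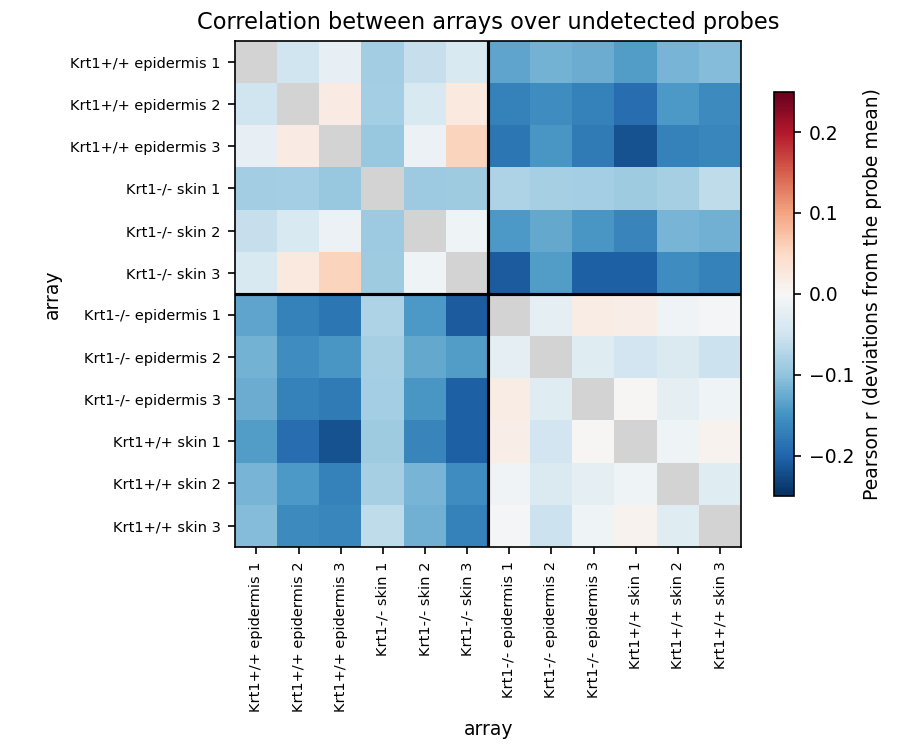
Pearson correlation between arrays over the 16240 probes undetected on every array, after subtracting each probe's mean; colour gives the correlation, grey cells are an array with itself, and the black lines part the 2 array sets. Arrays of different sets correlate below arrays of the same set, except for Krt1-/- skin 1, which correlates no better with its own set (−0.0940 to −0.0840) than with the other (−0.0894 to −0.0644).

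The 10 genes that rose most in Krt1-/- epidermis include 4 small proline-rich genes and 4 genes of proteases, inhibitors or antimicrobial peptides. Epgn, a ligand of the epidermal growth factor receptor, was 65.7-fold higher (log2 6.04 ± 0.267 SE, 3 arrays against 3, adjusted p = 1.9e-08). Krt6b, a keratin of wounded and stressed epidermis, was 65.01-fold higher (log2 6.02 ± 0.639 SE, adjusted p = 2.3e-05), a fold that may be compressed because its Krt1-/- signals of 11482 to 19828 lie near the ceiling of the arrays. The small proline-rich proteins, cross-linked precursors of the cornified envelope, followed with Sprr2e 57.5-fold, Sprr2g 42.8-fold, Sprr2k 32.9-fold and Sprr2f 30.5-fold higher. The protease inhibitors Spink7 and Slpi were 42.9-fold and 36.6-fold higher, the kallikrein protease Klk6 38.8-fold, and the antimicrobial peptide Defb4 28.5-fold. Sprr2k, Sprr2f and Defb4 were each detected on only 1 of 3 Krt1+/+ epidermis arrays, and Sprr2 genes are near-identical copies that a probe may not separate. All 10 of these genes rose in skin too, and all 10 passed in the average over both tissues.

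Among the genes fixed in advance, the alarmin cytokine Il33 was 27.5-fold higher in Krt1-/- epidermis (log2 4.78 ± 0.442 SE, adjusted p = 8.5e-06, detected on 2 of 3 Krt1+/+ arrays). The stress keratins Krt6a (detected on 2 of 3 Krt1+/+ arrays) and Krt16 were 26.1-fold and 6.51-fold higher, though signals near the ceiling may compress the fold of Krt16, and the calprotectin subunits S100a8 and S100a9 24.4-fold and 25.5-fold. Tslp, a cytokine made by stressed keratinocytes, was undetected on all 3 Krt1+/+ arrays and at least 4.61-fold higher (adjusted p = 0.0012). Krt5, a basal keratin, rose 2.80-fold (adjusted p = 0.0071). The cornified envelope protein Ivl rose 1.51-fold (adjusted p = 0.016), and that call was lost without Krt1-/- epidermis replicate 2 (adjusted p = 0.0511). Krt10, the partner of keratin 1, changed by −0.02 on the log2 scale (adjusted p = 0.96), Krt14 by −0.03, Krt17 by 0.07 and Lor by −0.12, and none of them passed. The probes of Krt10, Krt14 and Lor read 11004 to 22973 over the 12 arrays, where the brightest probe of an array reads 21229 to 28206, so a change near this ceiling may be compressed and its absence is not shown. Il18 changed by −0.76 (adjusted p = 0.072) and passed only without Krt1-/- epidermis replicate 1 (−1.11, adjusted p = 0.0131). Krt2 and Flg were not analysed here.

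Wfdc21, which encodes a secreted whey acidic protein family member, fell most, by 4.61 ± 0.289 SE on the log2 scale, to 24.4-fold lower (adjusted p = 6.0e-07). Dapl1 was 17.7-fold and Arhgef26 15.6-fold lower, Selenop 11.97-fold, Top2b 11.8-fold, Stmn1 11.1-fold, Mxi1 10.5-fold, Lypla1 10.4-fold and Morf4l1b 10.3-fold. The tenth, Rpl22l1, fell by 3.44 on the log2 scale. In skin 0 of these 10 fell and 8 rose. Only 4 of them passed in the average over both tissues: Wfdc21, Dapl1, Arhgef26 and Stmn1. A further probe of Selenop (0.34) and one of Lypla1 (0.63) pointed upward without passing. In total 1819 genes rose and 2030 fell in Krt1-/- epidermis (3849 of 12099), of which 1710 changed over 2-fold.

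Of the gene lists, 8 rose and 1 fell in Krt1-/- epidermis, and 0 of them passed with an estimated correlation. Small proline-rich protein genes rose in 11 of 13 measured members and fell in 0 (11 and 0 adjusted over the list alone), Sprr1b by 8.13-fold (adjusted p = 8.2e-13; adjusted p = 0.154 with an estimated correlation). Interferon response genes rose in 16 of 22 and fell in 0 (18 and 0 adjusted over the list alone), among them Usp18 by 11.3-fold, Oas1g by 6.10-fold and Ifi35 by 4.19-fold (adjusted p = 7.1e-08; adjusted p = 0.623 with an estimated correlation). Their median log2 change was 1.24, or 1.15 with undetected members at their bound. Alarmins and antimicrobial proteins rose in 12 of 16 and fell in 0 (12 and 0 adjusted over the list alone), Defb14 by 9.81-fold (adjusted p = 3.0e-06; adjusted p = 0.328 with an estimated correlation). Epidermal proteases and inhibitors rose in 12 of 28 and fell in 2 (13 and 2 adjusted over the list alone), with Serpinb6c 9.06-fold higher and the cystatin Stfa3 5.70-fold lower (adjusted p = 5.4e-04; adjusted p = 0.623 with an estimated correlation). On average over both tissues Stfa3 rose instead (1.21). Keratinocyte cytokines rose in 9 of 19 and fell in 2 (9 and 3 adjusted over the list alone), Hbegf by 9.87-fold and Il1b by 4.72-fold (adjusted p = 0.010; adjusted p = 0.623 with an estimated correlation).

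Genes of barrier lipid synthesis rose in 11 of 23 members in Krt1-/- epidermis and fell in 1 (12 and 1 adjusted over the list alone), with Degs2 8.07-fold and Alox12b 4.38-fold higher and Sptlc3 2.20-fold lower (adjusted p = 0.0054; adjusted p = 0.623 with an estimated correlation). Sptlc3 rose on average over both tissues (0.55), and a further probe of it changed by only −0.11 in epidermis. Cornified envelope genes rose in 7 of 17 and fell in 1 (7 and 1 adjusted over the list alone), Rptn by 19.9-fold, Cnfn by 6.64-fold and Tgm1 by 3.62-fold (adjusted p = 0.018; adjusted p = 0.623 with an estimated correlation). Chemokines rose in 6 of 20 and fell in 1 (7 and 1 adjusted over the list alone), Cxcl16 by 2.81-fold and Ccl20 by at least 3.48-fold (adjusted p = 0.031; adjusted p = 0.623 with an estimated correlation). The chemokine call was lost without Krt1-/- replicate 3 (0.0738), Krt1+/+ replicate 1 (0.0547) or Krt1+/+ replicate 3 (0.0506) of epidermis, and under 4 processing alternatives. Hair follicle markers fell in 5 of 18 members and rose in 0 (0 and 5 adjusted over the list alone), with Gata3 3.31-fold, Sox9 2.52-fold and Shh 2.23-fold lower (adjusted p = 0.018; adjusted p = 0.663 with an estimated correlation). That call was lost with the rotation test fry (0.121), and without Krt1-/- replicate 3 (median −0.68, adjusted p = 0.0787) or Krt1+/+ replicate 1 of epidermis (median −0.35, adjusted p = 0.134), against a median of −1.04 with all arrays.

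Other lists did not pass in epidermis but held members that changed. The late cornified envelope genes split, with 6 of 18 higher, led by Lce3f (27.9-fold) and Lce3e (19.1-fold), and 8 lower; their median was −0.51, their mean 0.39 and the test pointed down (adjusted p = 0.79). Of 8 stress and wound keratins 3 rose, the Krt6a, Krt6b and Krt16 named above, while the median was −0.06, the mean 1.54 and the test pointed up (adjusted p = 0.143). Median, mean and test also differed in sign for the macrophage and dendritic cell markers (−0.02, 0.02 and up) and the nerve markers (0.07, −0.18 and down). Tight junction genes rose in 1 of 13 and fell in 3 (adjusted p = 0.376), with Tjp1 6.77-fold lower, though not on average over both tissues (−0.08, adjusted p = 0.777). Erythroid markers changed in 0 of 6 (adjusted p = 0.143) and passed only without Krt1+/+ epidermis replicate 3 (0.00956). With fry in place of camera the stress keratin (0.0122), tight junction (0.0147) and oxidative stress lists (0.0044) passed in epidermis.

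**Figure D3:**
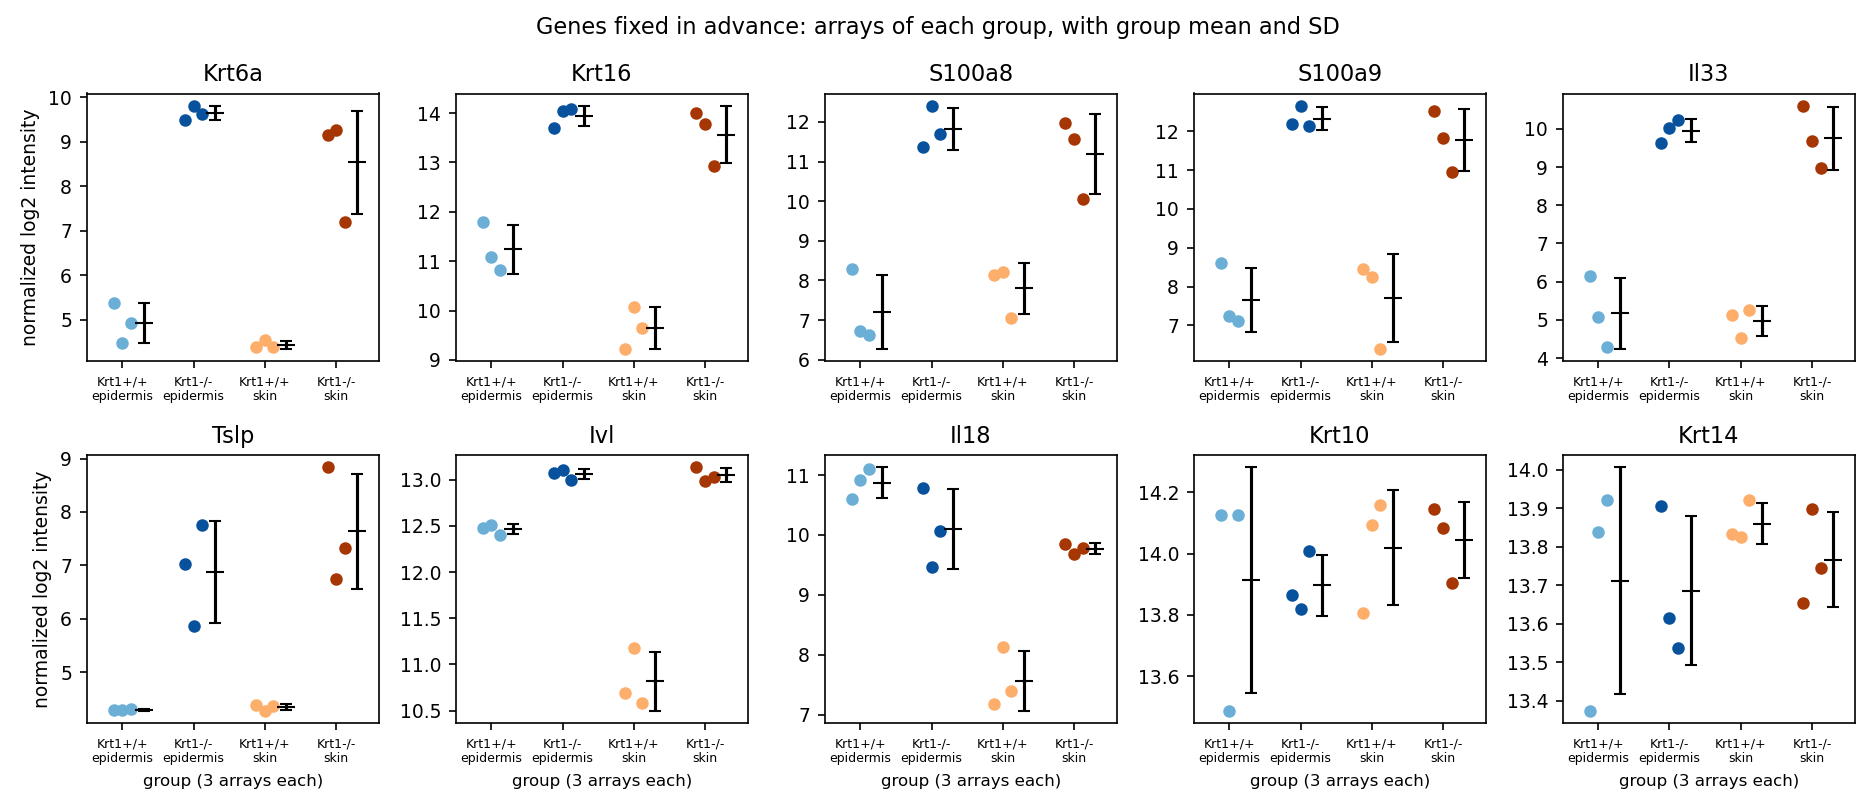
Normalized log2 intensity of 10 genes fixed in advance on each array (points) with the mean and SD of each group of 3 (bars); each panel has its own vertical scale. Krt6a, Krt16, S100a8, S100a9, Il33, Tslp and Ivl are higher in Krt1-/- in both tissues, Il18 in skin, while Krt10 and Krt14, read near the ceiling of the arrays, differ by no more than 0.09 on the log2 scale.

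Of the 10 genes that rose most in Krt1-/- skin, 7 are small proline-rich, late cornified envelope or cornified envelope genes. Lce3f, a late cornified envelope gene, was 155-fold higher (log2 7.27 ± 0.302 SE, 3 arrays against 3, adjusted p = 4.2e-09), and Lce3e 57.8-fold. The small proline-rich genes Sprr2g, Sprr2e, Sprr2h and Sprr2f were 134-fold, 108-fold, 104-fold and 68.0-fold higher. Slpi was 118-fold higher, the cornified envelope gene Rptn 91.0-fold, Krt6b 90.3-fold and Epgn 59.6-fold (log2 5.90 ± 0.267 SE, adjusted p = 8.5e-09). Sprr2e and Sprr2f were detected on 1 of 3 Krt1+/+ skin arrays and Sprr2g on 2 of 3, and copies of the Sprr2 and Lce3 families may share a probe's signal. All 10 genes also rose in epidermis and passed in the average.

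Among the genes fixed in advance, Il33 was 27.5-fold higher in Krt1-/- skin (log2 4.78 ± 0.442 SE, adjusted p = 7.3e-06, detected on 2 of 3 Krt1+/+ arrays), as it was in epidermis. Krt6a was 17.1-fold higher (detected on 1 of 3 Krt1+/+ arrays), S100a9 16.8-fold, Krt16 15.1-fold and S100a8 10.5-fold. Tslp was undetected on all 3 Krt1+/+ arrays and at least 8.47-fold higher (adjusted p = 2.3e-04). Ivl rose 4.71-fold and the cytokine Il18 4.61-fold (adjusted p = 1.8e-04). Krt5 fell 2.63-fold (log2 −1.39, adjusted p = 0.011), a call lost without Krt1+/+ skin replicate 2 (adjusted p = 0.0513) and opposite to its rise in epidermis. Krt17 rose 1.48-fold (adjusted p = 0.029), and that call was lost without Krt1-/- skin replicate 1 (0.076) or 2 (0.0864) or Krt1+/+ skin replicate 2 (0.052) or 3 (0.106). Krt10 (0.03), Krt14 (−0.09) and Lor (0.13), read near the ceiling, did not pass.

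Krt1 was the gene that fell most in Krt1-/- skin. Ptms was 11.6-fold lower (log2 −3.53 ± 0.522 SE, adjusted p = 2.8e-04), Selenow 9.20-fold, Bcat2 7.92-fold, the collagen gene Col6a2 7.87-fold, the mast cell tryptase Tpsb2 7.68-fold, Ctsa 6.60-fold, the peptidase Anpep 6.59-fold and fibronectin, Fn1, 5.96-fold. Pou6f1 was undetected on all 3 Krt1-/- skin arrays and at least 5.54-fold lower. Of these 10 genes 1 also fell in epidermis, Pou6f1, and 5 rose there; 7 passed in the average, while Ptms, Selenow and Bcat2 did not. Of the further probes, 3 of Ctsa and 2 of Fn1 were lower without passing, and 1 of Ctsa pointed upward (0.66). In total 1747 genes rose and 1971 fell in Krt1-/- skin (3718 of 12099), 1541 of them by over 2-fold. With median centring, which moves the median of all genes, the balance turned, to 2211 rises and 1342 falls.

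In Krt1-/- skin 17 lists rose and 1 fell, and 0 of them passed with an estimated correlation. Small proline-rich genes rose in 12 of 13 members (13 adjusted over the list alone), Sprr1b by 34.8-fold, with a median of 4.89, or 4.68 with undetected members at their bound (adjusted p = 8.9e-18; adjusted p = 0.0597 with an estimated correlation). Epidermal proteases and inhibitors rose in 20 of 28 and fell in 1 (22 and 1 adjusted over the list alone), Klk6 by 54.7-fold, Stfa3 by 30.4-fold and Klk7 by 6.69-fold (adjusted p = 5.5e-14; adjusted p = 0.0968 with an estimated correlation). Keratinocyte cytokines rose in 13 of 19 and fell in 0 (14 and 0 adjusted over the list alone), with the interleukin 36 genes Il1f6 and Il1f8 15.2-fold (detected on 1 of 3 Krt1+/+ arrays) and 9.01-fold higher (adjusted p = 3.8e-10; adjusted p = 0.0968 with an estimated correlation). Late cornified envelope genes rose in 11 of 18 and fell in 1 (13 and 1 adjusted over the list alone), Lce3c by 16.04-fold (adjusted p = 1.2e-08; adjusted p = 0.108 with an estimated correlation). Alarmins rose in 12 of 16 and fell in 0 (12 and 1 adjusted over the list alone), Defb14 by 20.9-fold and Defb1 by 17.8-fold (adjusted p = 1.1e-06; adjusted p = 0.0968 with an estimated correlation). Cornified envelope genes rose in 11 of 17 and fell in 0 (13 and 0 adjusted over the list alone), Cnfn by 4.04-fold (adjusted p = 2.1e-06; adjusted p = 0.0968 with an estimated correlation). The late cornified envelope (median −1.02), protease (−0.87), keratinocyte cytokine (−0.53) and cornified envelope lists (−0.42) are lower in Krt1+/+ skin than in epidermis, and so are the small proline-rich genes (−0.64, or −0.32 with undetected members at their bound). The medians of all 6 dermal marker lists lay below 0 in Krt1-/- skin, and whether a larger share of epidermis in these samples contributes to these rises was not tested. A larger share alone, with unchanged epidermis, would not lift Krt1-/- skin above Krt1+/+ epidermis. As deviations from each gene's mean, small proline-rich medians were 1.81 to 2.50 in Krt1-/- skin, against −1.57 to −1.36 in Krt1+/+ epidermis. Those of alarmins were 0.39 to 1.12 against −0.63 to −0.52. For both lists these values argue against a share alone. Late cornified envelope medians overlapped (0.26 to 0.46 against −0.01 to 0.52).

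Lists of lipid and sterol synthesis rose in Krt1-/- skin. Barrier lipid (median −0.62), cholesterol (−0.78), early suprabasal (−0.60) and desmosome lists (−0.56) are lower in Krt1+/+ skin than in epidermis, so the same untested share of epidermis applies to them. Barrier lipid genes rose in 15 of 23 members and fell in 0 (16 and 0 adjusted over the list alone), with Abca12, the lipid transporter of lamellar granules, 10.95-fold and Degs2 6.16-fold higher (adjusted p = 3.9e-08; adjusted p = 0.122 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 17 and fell in 0 (11 and 0 adjusted over the list alone), Idi1 by 9.92-fold and Cyp51 by 3.01-fold (adjusted p = 1.1e-05; adjusted p = 0.137 with an estimated correlation). Idi1 did not pass on average over both tissues (0.19, adjusted p = 0.387), nor did a further probe of Abca12 in skin (0.43). Early suprabasal genes rose in 11 of 19 and fell in 0 (12 and 1 adjusted over the list alone), Dsc1 by 10.02-fold and Endou by 5.07-fold (adjusted p = 4.5e-04; adjusted p = 0.331 with an estimated correlation). Desmosome and junction genes rose in 5 of 16 and fell in 1 (8 and 1 adjusted over the list alone), the connexins Gjb6 by 5.83-fold and Gjb2 by 4.01-fold (adjusted p = 0.0030; adjusted p = 0.231 with an estimated correlation). A further probe of Gjb2 was higher without passing (1.01, adjusted p = 0.0947). Stress and wound keratins rose in 4 of 8 and fell in 0, with the same counts adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.225 with an estimated correlation).

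Stress and immune lists rose in Krt1-/- skin as well. Interferon response genes rose in 10 of 22 and fell in 0 (12 and 0 adjusted over the list alone), Oas1g by 3.65-fold (adjusted p = 3.3e-05; adjusted p = 0.331 with an estimated correlation). Oxidative stress genes rose in 9 of 23 and fell in 3 (10 and 3 adjusted over the list alone), the cystine transporter Slc7a11 by 11.04-fold (adjusted p = 0.0011; adjusted p = 0.0732 with an estimated correlation). Heat shock and unfolded protein genes rose in 9 of 23 and fell in 2 (11 and 3 adjusted over the list alone), Hspa1b by 12.4-fold (adjusted p = 0.0059; adjusted p = 0.127 with an estimated correlation). Inflammasome and interleukin 1 genes rose in 7 of 17 and fell in 0 (8 and 0 adjusted over the list alone), Nfkbiz by 4.24-fold (adjusted p = 0.0023; adjusted p = 0.232 with an estimated correlation). Immediate early genes rose in 7 of 20 and fell in 1 (8 and 1 adjusted over the list alone), Ier3 by 2.96-fold (adjusted p = 0.020; adjusted p = 0.471 with an estimated correlation), a call lost without Krt1-/- skin replicate 1 (0.0775) or Krt1+/+ skin replicate 2 (0.0661) and with fry (0.0967). Neutrophil markers rose in 3 of 7 and fell in 0 (4 and 0 adjusted over the list alone), Retnlg by 3.41-fold (adjusted p = 0.020; adjusted p = 0.114 with an estimated correlation), a call lost without Krt1+/+ skin replicate 3 (0.0753) and with median centring (0.0622).

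Of the markers of dermal cell types, only the endothelial list passed in Krt1-/- skin. Endothelium and pericyte markers fell in 8 of 11 members and rose in 0, with the same counts adjusted over the list alone, Pecam1 by 3.59-fold and Pdgfrb by 2.17-fold (adjusted p = 2.1e-04; adjusted p = 0.0968 with an estimated correlation). Dermal fibroblast markers fell in 5 of 15 and rose in 0 (0 and 7 adjusted over the list alone), Col6a2 by 7.87-fold and Col1a1 by 4.09-fold, but the list did not pass (median −0.81, adjusted p = 0.052); it passed under 5 processing alternatives (0.00638 to 0.0202) and without each of 4 arrays, Krt1-/- epidermis replicate 2 (0.0146) or 3 (0.0150), Krt1-/- skin replicate 1 (0.0333) or Krt1+/+ skin replicate 2 (0.0295). The call of Col1a1 in skin was lost without Krt1+/+ skin replicate 1 (adjusted p = 0.0534) and with median centring (0.0501). In epidermis Col1a1 was higher on the Krt1-/- arrays (log2 7.23, 5.55 and 8.90) than on the Krt1+/+ arrays (5.22, 4.67 and 5.12). Its average over both tissues joins these opposite changes and did not pass (0.09). A further probe of Pecam1 was lower in skin without passing (−0.50). The lists of mast cell (adjusted p = 0.0876), skeletal muscle (0.127), adipocyte (0.372) and nerve markers (0.966) did not pass. The mast cell list passed under 4 processing alternatives (0.0203 to 0.0356) and without Krt1-/- skin replicate 1 (0.0333) or Krt1-/- epidermis replicate 2 (0.02565) or 3 (0.0420). The muscle list passed without Krt1-/- skin replicate 2 (adjusted p = 0.0182) or Krt1+/+ skin replicate 2 (0.00862), and the adipocyte list without Krt1-/- skin replicate 3 (−1.04, 0.00556). Hair follicle markers (median −0.69) did not pass in skin. They passed with median centring (0.0304), no detection filter (0.0451), only the skin arrays (0.0477), and without Krt1-/- skin replicate 2 (0.00655) or Krt1+/+ skin replicate 3 (0.0325). The proliferation list (−0.47) passed in skin only with no detection filter (0.0265) or without Krt1-/- skin replicate 1 (0.0302), and the basal list (−0.33) only without replicate 2 (0.0494). In epidermis the endothelial median was 0.15 and the fibroblast median 0.59 (0.40 with undetected members at their bound), neither passing. Without Krt1-/- epidermis replicate 2 the fibroblast (1.03, adjusted p = 0.00336), skeletal muscle (1.10, 0.00485) and mast cell lists (0.89, 6.6e-04) rose in epidermis. The mast cell list also passed there without Krt1+/+ epidermis replicate 2 (0.0473) and with no detection filter (0.0317). With all arrays its epidermis median was 0.69, or 0.37 with undetected members at their bound. The fibroblast median, as a deviation from each gene's mean over the arrays, was −2.22 and −1.28 on Krt1-/- epidermis arrays 1 and 3, above the −2.74 to −2.46 of Krt1+/+ epidermis, and −3.24 on array 2, below it. Median, mean and test differed in sign for erythroid markers (−0.14, −0.10 and up) in skin, and for extracellular matrix genes (0.06, −0.07 and down) only while undetected members are not at their bound (median −0.00178).

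The changes of single genes only partly coincided between the tissues. Of the genes that rose, 401 rose in both tissues, where independent lists of these sizes would share 263, and 269 fell in both, where 331 would be shared. Opposite changes were more frequent: 398 genes rose in epidermis and fell in skin (296 if independent), and 682 fell in epidermis and rose in skin (293 if independent). Across all 12099 genes, which are not independent replicates, the log2 changes of the tissues correlated at r = −0.0485 (rho = −0.113). Of 46 genes over 8-fold higher in epidermis, 41 rose in skin and 1 fell, and of 80 over 8-fold higher in skin, 50 rose in epidermis and 22 fell. Of 18 genes over 8-fold lower in epidermis, 0 fell in skin and 15 rose. A difference between the array sets enters the genotype contrasts of the tissues with opposite signs. It would by itself give more opposite changes and a negative correlation, so these may be technical.

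**Figure D4:**
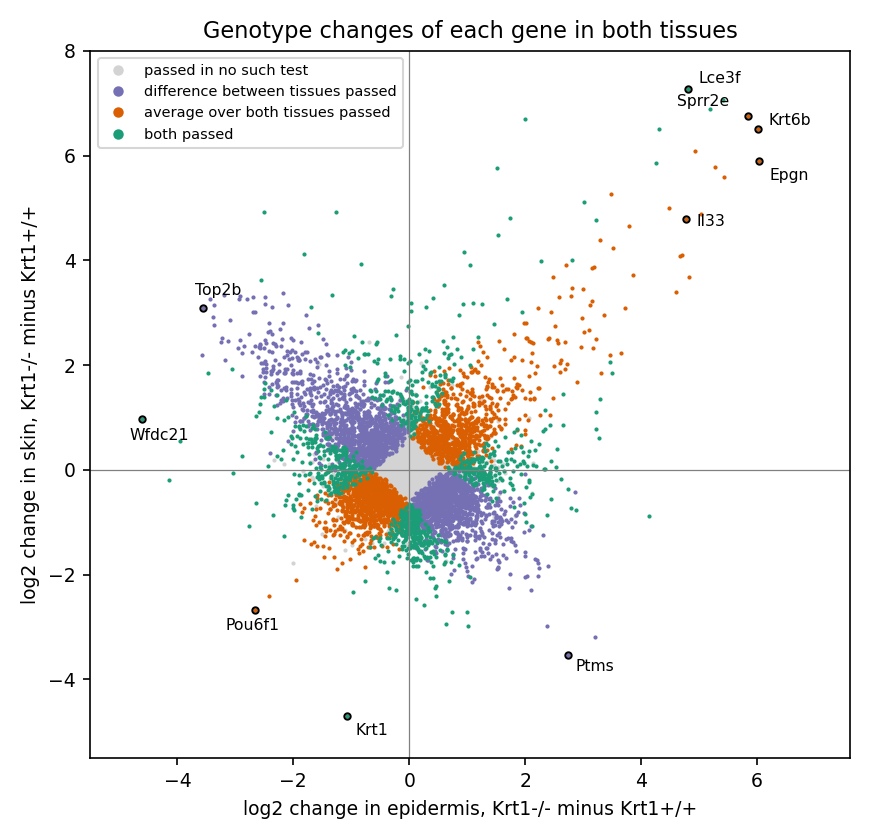
Log2 change of each of 12099 genes between Krt1-/- and Krt1+/+ in epidermis (horizontal) and skin (vertical), with colours for the test of the average over both tissues and of the difference between them. Epgn, Krt6b, Sprr2e, Il33 and Lce3f lie high in both tissues, while Top2b fell in epidermis and rose in skin.

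Averaged over both tissues, 1320 genes rose and 1604 fell in Krt1-/- (2924 of 12099), 506 by over 2-fold. With median centring the balance turned, to 1697 rises and 1112 falls. An additive difference between the array sets cancels in this average where all arrays of a set carry it alike. The largest rises were those of Sprr2e (78.7-fold, log2 6.30 ± 0.172 SE, 6 arrays against 6, adjusted p = 9.8e-11), Krt6b (76.6-fold), Sprr2g (75.7-fold), Lce3f and Slpi (each 65.7-fold), Epgn (62.6-fold), Klk6 (46.1-fold), Sprr2f (45.5-fold) and Rptn (42.6-fold), together with Spink7, which was undetected in Krt1+/+ skin. Il33 rose 27.5-fold, Krt6a 21.1-fold, S100a9 20.7-fold, S100a8 16.03-fold, Krt16 9.92-fold and Ivl 2.67-fold, and Tslp rose as well (adjusted p = 5.7e-05). Il18 rose 1.65-fold (adjusted p = 0.027), a call lost under 3 processing alternatives (0.0557 to 0.0704) and without Krt1+/+ epidermis replicate 1 (0.0604), Krt1-/- epidermis replicate 1 (0.0584), Krt1-/- skin replicate 1 (0.0562), or Krt1+/+ skin replicate 1 (0.0716) or 3 (0.0622). Krt10 (0.00), Krt14 (−0.06), Krt5 (0.05), Krt17 (0.32, adjusted p = 0.087) and Lor (0.00) did not pass, and Krt17 passed under 4 processing alternatives (0.00787 to 0.0485).

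Falls on average were smaller: 42 genes rose by over 8-fold and 0 fell by as much. Krt1 fell by 2.89 on the log2 scale (adjusted p = 3.3e-04), though its epidermis arrays overlapped between genotypes. The falls named next are of genes whose arrays lay apart in both tissues. Pou6f1, a POU family transcription factor, was detected on all 6 Krt1+/+ arrays and on none of the Krt1-/- arrays (adjusted p = 4.7e-08). Skint9, of a family of immunoglobulin-like genes expressed in epidermis, was 5.33-fold lower (log2 −2.41 ± 0.400 SE, adjusted p = 9.3e-04), Tesc 4.08-fold, Bbox1 3.79-fold, Sp5 3.27-fold, the basal keratin Krt15 3.15-fold, Prss35 3.12-fold, Pdlim4 3.04-fold, Pcdh20 2.99-fold and the class II antigen gene H2-Ab1 2.97-fold. A further probe of Pdlim4 and one of H2-Ab1 were lower without passing. In both tissues alike, with the average passing and the test of a difference between tissues not passing, 354 genes rose and 257 fell.

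On average 18 lists rose and 5 fell in Krt1-/-. With an estimated correlation 3 of these calls held. Small proline-rich genes rose in 13 of 13 members, also adjusted over the list alone, Sprr2h by 20.4-fold and Sprr1b by 16.8-fold (adjusted p = 3.7e-24; adjusted p = 0.0228 with an estimated correlation). Alarmins rose in 13 of 16 and fell in 0 (14 and 0 adjusted over the list alone), Defb14 by 14.3-fold and Defb1 by 5.86-fold (adjusted p = 1.0e-11; adjusted p = 0.044 with an estimated correlation). Oxidative stress genes rose in 10 of 23 and fell in 2 (11 and 3 adjusted over the list alone), Slc7a11 by 8.81-fold, the glutathione transferase Gsta4 by 7.37-fold and Srxn1 by 4.94-fold (adjusted p = 4.1e-04; adjusted p = 0.044 with an estimated correlation). Proteases and inhibitors rose in 22 of 28 and fell in 0, also adjusted over the list alone, Serpinb6c by 11.5-fold and Csta1 by 5.55-fold (adjusted p = 2.1e-17; adjusted p = 0.0682 with an estimated correlation). Interferon response genes rose in 16 of 22 and fell in 0 (17 and 0 adjusted over the list alone), Usp18 by 6.39-fold (adjusted p = 1.3e-12; adjusted p = 0.127 with an estimated correlation). Keratinocyte cytokines rose in 12 of 19 and fell in 0 (15 and 0 adjusted over the list alone), Hbegf by 5.95-fold (adjusted p = 4.0e-12; adjusted p = 0.0513 with an estimated correlation).

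Of the other lists that rose on average, barrier lipid genes rose in 16 of 23, Degs2 by 7.05-fold (17 adjusted over the list alone; adjusted p = 3.0e-11; adjusted p = 0.0743 with an estimated correlation). Cornified envelope genes rose in 9 of 17 (10, and 1 lower, adjusted over the list alone; adjusted p = 2.5e-07; adjusted p = 0.0743 with an estimated correlation). Cholesterol genes rose in 9 of 17, Cyp51 by 2.76-fold (10 adjusted over the list alone; adjusted p = 2.1e-06; adjusted p = 0.127 with an estimated correlation). Early suprabasal genes rose in 10 of 19 (12 adjusted over the list alone; adjusted p = 1.1e-05; adjusted p = 0.185 with an estimated correlation). Late cornified envelope genes rose in 6 of 18 and fell in 1, also adjusted over the list alone (adjusted p = 4.1e-04; adjusted p = 0.231 with an estimated correlation). The lists of inflammasome (7 of 17, adjusted p = 4.1e-04), immediate early (6 of 20, 0.0035), stress keratin (3 of 8, 0.0035), chemokine (8 of 20 with 1 lower, 0.0037), neutrophil (4 of 7, 0.0063), desmosome (5 of 16 with 2 lower, 0.010) and heat shock genes (5 of 23, 0.027) rose too, and with an estimated correlation their adjusted p lay between 0.0743 and 0.345. Adjusted over the list alone these counts were 7, 6, 4 with 1 lower, 8 with 1 lower, 4, 6 with 2 lower, and 5. The heat shock call was lost without Krt1+/+ skin replicate 2 (0.0665).

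The lists that fell on average were hair follicle, proliferation, endothelial, basal layer, and T cell and Langerhans cell markers, the last with 3 of 6 members lower (adjusted p = 0.020; adjusted p = 0.185 with an estimated correlation). Hair follicle markers fell in 4 of 18 and rose in 0, also adjusted over the list alone, with Shh 2.77-fold and Sox9 1.96-fold lower (adjusted p = 9.5e-04; adjusted p = 0.432 with an estimated correlation). Proliferation genes fell in 7 of 25 and rose in 1 (8 and 1 adjusted over the list alone), all of the named members by less than 2-fold, Nusap1 by 1.41-fold (adjusted p = 0.0035; adjusted p = 0.432 with an estimated correlation). The call of Nusap1 was lost with median centring (adjusted p = 0.111), and a further probe of it changed by 0.01. Endothelial markers fell in 6 of 11, also adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.132 with an estimated correlation). Basal layer and hemidesmosome genes fell in 5 of 15, also adjusted over the list alone, Krt15 by 3.15-fold and Lamb3 by 1.89-fold (adjusted p = 0.029; adjusted p = 0.378 with an estimated correlation). The basal call was lost with median centring (0.224) and without Krt1-/- epidermis replicate 1 (0.0591), Krt1+/+ epidermis replicate 3 (0.0634), Krt1-/- skin replicate 3 (0.0954) or Krt1+/+ skin replicate 3 (0.0708). Median, mean and test differed in sign for tight junction genes (0.02, or −0.04 with undetected members at their bound, −0.08 and up) and macrophage markers (0.03, −0.13 and down).

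**Figure D5:**
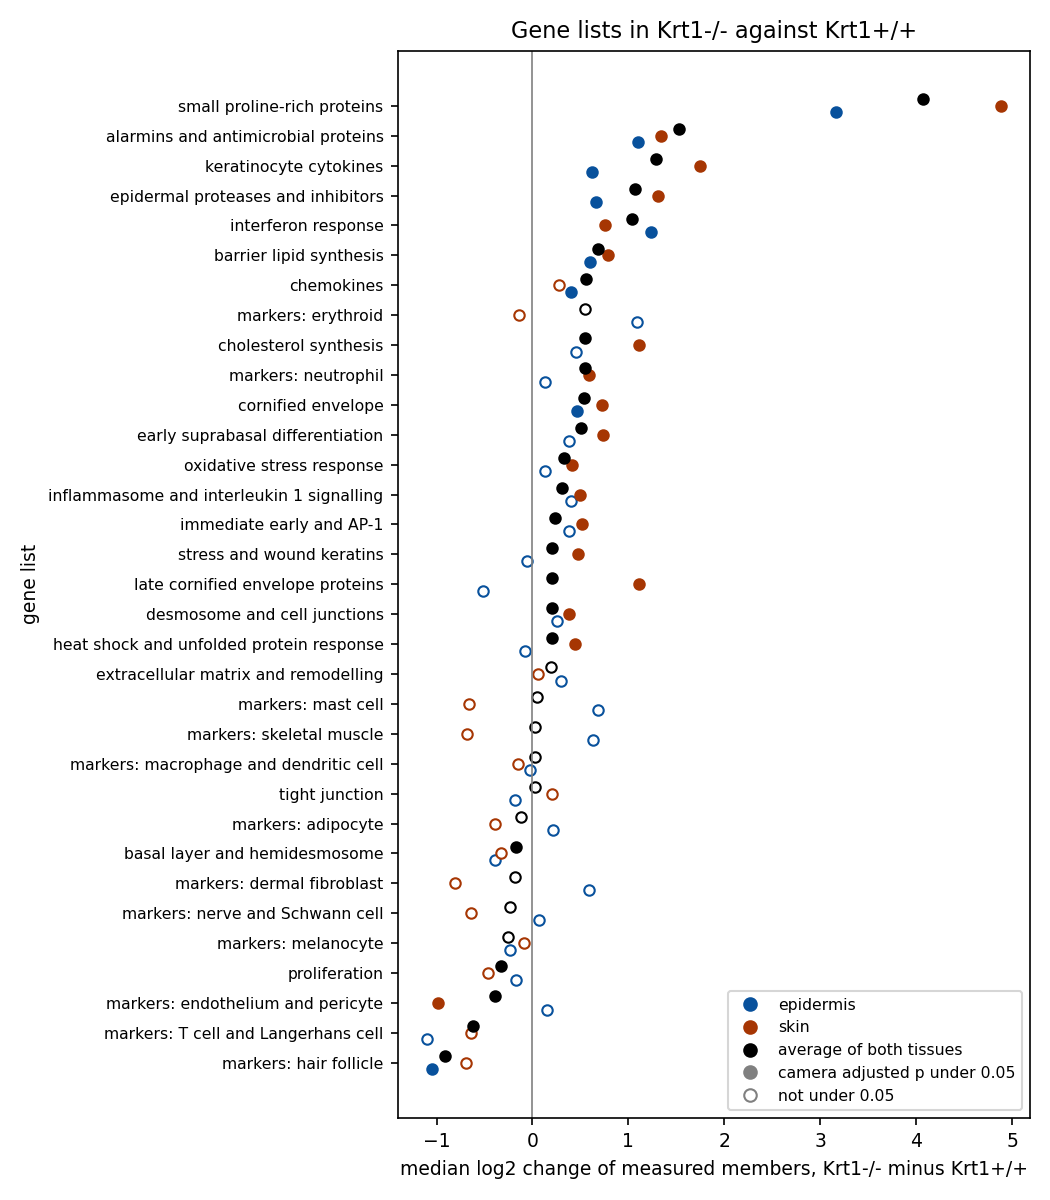
Median log2 change of the measured members of each of 33 gene lists (Krt1-/- minus Krt1+/+) in epidermis, in skin and averaged over both; filled points passed camera with its preset correlation, open points did not. The small proline-rich genes stand highest in all 3 (3.16, 4.89 and 4.07), and the hair follicle markers lie below 0 in all 3.

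The genotype effect differed between the tissues for 3743 genes, 1914 of them higher and 1829 lower in epidermis relative to skin. With median centring the balance turned, to 1466 higher and 2042 lower. This contrast also sets one array set against the other. Selenow (log2 6.40 ± 0.689 SE, adjusted p = 1.5e-05), Ptms (6.26), Bcat2 (5.36), Rbp2 (5.02) and Vat1 (4.40) were the most positive. The protease inhibitor Stfa3 (−7.44 ± 0.469 SE, adjusted p = 1.8e-07), Rpl22l1 (−6.69), Top2b (−6.65), Lypla1 (−6.52) and Mxi1 (−6.30) were the most negative, and a further probe of Lypla1 gave 0.76 without passing. Effects were lower in epidermis for 13 of 18 late cornified envelope genes (adjusted p = 1.6e-05), 9 of 28 proteases and inhibitors, with 2 higher (0.0078), 5 of 13 small proline-rich genes (0.0086) and 7 of 19 keratinocyte cytokines (0.047). They were higher in epidermis for 7 of 11 endothelial (0.0078), 6 of 10 mast cell (0.038) and 5 of 14 skeletal muscle markers (0.047). Each of these 7 lists had an adjusted p = 0.789 with an estimated correlation. Adjusted over the list alone, the counts were 13, 10 with 2 higher, 7, 7, 8, 6 and 5. Median, mean and test differed in sign for alarmins (0.36, −0.09 and down), immediate early (−0.13, 0.06 and down), proliferation (0.43, −0.09 and up), melanocyte (0.03, −0.10 and down) and basal layer genes (−0.03, 0.02 and up).

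Full-thickness skin of Krt1+/+ mice differed from Krt1+/+ epidermis in the tissues it holds, and 2395 genes were higher and 2652 lower in skin (5047 of 12099), or 1805 and 3813 with median centring. Collagen Col1a1 was 453-fold higher in skin (log2 8.82 ± 0.565 SE, 3 arrays against 3, adjusted p = 5.2e-08, detected on 2 of 3 epidermis arrays). The muscle genes Tnnc2 (436-fold), Actc1 (256.5-fold) and Myh8 (220.3-fold) followed, and Sln, undetected on all 3 epidermis arrays, was at least 202-fold higher. Epidermis was higher for Stfa3 (45.1-fold), Cstdc6 (35.0-fold), the kallikrein inhibitor Spink5 (29.6-fold), Wfdc21 (19.9-fold) and Top2b (17.5-fold). This contrast, too, sets one array set against the other, and the average over both genotypes, added after the data were seen, gave 2261 higher and 2872 lower genes and kept 3480 of the 5047 calls in direction.

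Of the marker lists, those of muscle, fibroblasts, vessels, mast cells, fat, macrophages and nerve were higher in Krt1+/+ skin than in epidermis, while those of neutrophils (adjusted p = 0.169), T and Langerhans cells (0.143), erythroid cells (0.0890) and hair follicle (0.677) did not pass. Skeletal muscle markers were higher for 13 of 14 members (adjusted p = 1.9e-11; adjusted p = 0.239 with an estimated correlation), dermal fibroblast for 13 of 15 (9.8e-11; 0.239), mast cell for 9 of 10 (2.1e-07; 0.239), adipocyte for 7 of 10 (5.8e-05; 0.325), macrophage for 9 of 14 with 1 lower (0.0014; 0.325), nerve for 3 of 5 with 1 lower (0.020; 0.260) and extracellular matrix genes for 5 of 16 with 1 lower (0.031; 0.325), each second value being the adjusted p with an estimated correlation. Endothelial markers were higher for 9 of 11 and passed with an estimated correlation too (adjusted p = 2.8e-09; adjusted p = 0.0339 with an estimated correlation). Adjusted over the list alone the counts were 13, 14 with 1 lower, 9, 8, 9 with 1 lower, 3 with 1 lower, 5 with 1 lower, and 11. Epidermal lists and melanocyte markers were lower in skin: late cornified envelope (14 of 18), proteases and inhibitors (16 of 28), barrier lipid (11 of 23), cholesterol (10 of 17), desmosome (8 of 16), proliferation (9 of 25), keratinocyte cytokine (8 of 19), early suprabasal (10 of 19), small proline-rich (6 of 13), cornified envelope (8 of 17) and melanocyte (7 of 11). Their adjusted p ran from 3.1e-05 to 0.020, and from 0.325 to 0.405 with an estimated correlation. Adjusted over the list alone, the counts of lower members were 16, 17, 11, 10, 8, 8, 8, 10, 6, 8 and 7. Median, mean and test differed in sign for hair follicle (−0.32, 0.30 and down) and immediate early genes (−0.01, 0.07 and down).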

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

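The tests of undetected probes, of exchanged labels, of fibroblast markers in epidermis by single arrays, of endothelial markers in epidermis and of averages over both tissues were chosen only after the result was seen. The genotype effect differed between epidermis and skin for 3743 of 12099 genes, more than the 2924 that passed on average. Undetected probes, which lie within background, separated the array sets by 0.1164 in correlation, the highest of 462 splits (next 0.0890), though Krt1-/- skin replicate 1 joined neither set, and the difference between tissues is the same contrast as the difference between these sets. Probes of the same gene also correlated less on this difference (r = 0.287) than on the average genotype effect (0.777), a gap of −0.4907 (95% interval −0.534 to −0.445 over 2000 resamples), and of probe pairs that both passed, 158 of 708 disagreed in direction against 2 of 528. Both values are what a technical difference between the array sets predicts, so much of this pattern may be technical. A true difference between epidermis and full-thickness skin stays open and was not tested apart from the sets.

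The Krt1 probe kept signal on the arrays labelled Krt1-/- epidermis (change −1.07, SE 0.585), while it fell 26.0-fold in skin. Exchanged epidermis labels are argued against by the small proline-rich genes, of which 11 of 13 rose in epidermis and 0 fell, as in full-thickness skin, where 12 rose and 0 fell; the correlation of the tissues' changes over genes called in skin, −0.05315, lies on the side that an exchange predicts but close to 0, and its cause was not tested. Krt1+/+ tissue mixed into these samples cannot be told apart from the rest. The epidermal genes that fell over 4-fold in skin, Krt15 (−0.97), Tesc (−1.96) and Skint9 (−2.41), had a median epidermis change of −1.96. That is beyond the change of Krt1 by less than 2 of its standard errors. A mixture alone would also limit the fall of every gene to about that of Krt1, while 18 genes fell over 8-fold in epidermis. Of these 15 rose and 0 fell in skin, so they cannot be kept apart from the array sets and do not decide. An array-set difference on this probe cannot be told apart either, since 1.471% of genes have an effect of the sets (the difference between tissues divided by 2) at least as large as its 1.81. A transcript of the targeted gene that the probe still reads would also show in full-thickness skin, which holds epidermis. There the probe read 183 to 319 on the Krt1-/- arrays, against 987 to 2921 in Krt1-/- epidermis. Krt1+/+ arrays read 1794 to 5915 in skin and 1417 to 5954 in epidermis. These values argue against such a transcript as the only explanation, though an array-set difference on this probe may contribute.

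In Krt1-/- skin endothelial markers were lower (median −0.98; adjusted p = 2.1e-04, or adjusted p = 0.0968 with an estimated correlation), and fibroblast markers had a median of −0.806 without passing (adjusted p = 0.052). A lower share of all non-epidermal tissue would lower the fibroblast, endothelial, adipocyte, muscle and nerve medians alike; all lay below 0, the largest gap between them was 0.5888 (endothelial against adipocyte markers, whose median moves from −0.393 to −1.04 without Krt1-/- skin replicate 3), and no pair passed a test of the difference (permutation test, adjusted p = 0.857), so a lower share cannot be told apart from separate changes with so few members. A technical difference between the array sets predicts the opposite change in epidermis, where the fibroblast median was 0.5925, as it predicts under the rule first written. With 2 undetected members at their bound this median was only 0.397. A condition on single arrays was added after the value of 0.5925 was seen. Since a Krt1-/- array, replicate 2 (−3.24), lay below all Krt1+/+ arrays, a technical difference cannot be told apart either. The endothelial median in epidermis was only 0.1503, which excluded that explanation under the floor first used (5 of 11 members undetected on every epidermis array); the floor was then moved, with the value known, to detection on fewer than 3 of 6 arrays (9 of 11 members), which leaves it open. A loss of dermal cells or of their transcripts in Krt1-/- skin stays possible and was not tested apart from these.

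The counts of genes were set against other splits of the same arrays. For epidermis (3849 genes, highest other split 0), skin (3718, highest other 39) and skin against epidermis (5047, highest other 0), 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the difference between tissues 1 of 100 splits, the real one, gave as many as 3743, a share under 0.05. The highest other, 2924, is the split that exchanges the genotypes in a single tissue, and the next gave 1296. For the average 2 of 100 splits gave as many as 2924, also a share under 0.05. The other, with 3743, follows the array sets, and the next gave 1287. Splits that mix groups also raise the spread within them, which favours the real split. These shares therefore cannot exclude a chance split of the arrays. Chance between animals was not tested, since the labels do not say that arrays of a group came from separate animals.

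Of the genes named for the genotype contrasts or their difference, these differed between the tissues in the test of the difference itself (log2, epidermis effect minus skin effect). Higher in epidermis were Selenow (6.40), Ptms (6.26), Bcat2 (5.36), Rbp2 (5.02), Vat1 (4.40), Col1a1 (4.26), Col6a2 (3.98), Ctsa (3.72), Krt1 (3.63), Tpsb2 (3.58), Anpep (3.46), Krt5 (2.88), Fn1 (2.83), Cd74 (2.08), Alox12b (2.04), Pecam1 (2.00), Ifi35 (1.70), Usp18 (1.64), Ccl20 (1.57), Krt15 (1.36) and Pdgfrb (1.17). Lower in epidermis among cornification and barrier genes were Sprr2h (−4.70), Abca12 (−3.74), Dsc1 (−3.65), Sptlc3 (−3.39), Csta1 (−2.86), Klk7 (−2.76), Lce3f (−2.47), Rptn (−2.19), Sprr1b (−2.10), Gjb6 (−1.78), Slpi (−1.69), Endou (−1.69), Sprr2g (−1.64), Ivl (−1.64), Lce3e (−1.60), Lce3c (−1.20) and Gjb2 (−0.95). Of other genes, Stfa3 (−7.44), Rpl22l1 (−6.69), Top2b (−6.65), Lypla1 (−6.52), Mxi1 (−6.30), Idi1 (−6.23), Hspa1b (−6.19), Morf4l1b (−6.14), Selenop (−5.77), Wfdc21 (−5.58), Tjp1 (−5.36), Stmn1 (−5.32), Il1f6 (−4.76), Arhgef26 (−4.52), Dapl1 (−3.94), Defb1 (−3.20), H2-Aa (−2.97), Il18 (−2.97), Il1f8 (−2.23), Gata3 (−2.02), Prss35 (−2.01), Bbox1 (−1.70), Pdlim4 (−1.50), Cd3e (−0.97), Cd3d (−0.94), Nusap1 (−0.94) and Sp5 (−0.89) were lower. Of 3025 detected probes without 1 gene, which the comparisons of genes leave out, 541 passed on average over both tissues (251 higher and 290 lower).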

How the results depend on the processing

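Averages over both tissues and over both genotypes, and tests of probes without 1 gene, were chosen only after the result was seen. Over all alternatives 4362 of 4426 values of named genes were counted as unchanged, 47 lost the call, 6 gained it and 11 took the opposite sign. A change of sign was counted only where the value passed in the main fit or in the alternative. Sign changes between values that passed in neither are thus among the unchanged. Of 2409 values of lists 2279 were unchanged in this sense, 68 lost the call, 59 gained it and 3 took the opposite sign. Many named genes were chosen for large changes, and leaving out arrays of the other tissue cannot move a contrast's log2 change, so much of this stability was fixed in advance. Of the alternatives for the genotype contrasts, only the average over both tissues cancels an additive array-set difference that all arrays of a set carry alike. It kept 48 of 60 values of named genes in epidermis and 55 of 62 in skin. Tested as probes, the counts rose to 6066 in epidermis, 6073 for the difference between tissues and 7919 for the average tissue contrast, since more features are tested. With at least 1.5-fold as threshold, 1719 genes passed in the average over both tissues and 3245 in the average tissue contrast. Median centring moved the median of all genes by 0.12 in skin, −0.13 for the difference between tissues, −0.22 for skin against epidermis and −0.15 for the average tissue contrast; rises were then 62.2% of calls in skin (against 47.0%), 60.4% on average (45.1%), 41.8% for the difference (51.1%), 32.1% for skin against epidermis (47.5%) and 28.9% in the average tissue contrast (44.0%). Other probes of a gene took the opposite sign without passing for Selenop (0.34) and Lypla1 (0.63) in epidermis, Ctsa in skin (0.66), Nusap1 on average (0.0139) and Lypla1 for the difference between tissues (0.76). The cause was not tested. The average over both tissues, in which each tissue has the same weight, gave Krt1 −2.89, against −1.07 in epidermis alone. It reversed Il18 (0.72), Sptlc3 (0.55), Stfa3 (1.21) and the late cornified envelope (0.21), heat shock (0.20) and endothelial (−0.39) lists of epidermis. The skin calls of Selenow (0.00105), Krt5 (0.046) and Col1a1 (0.095) were lost on average, with values close to 0 (adjusted p = 0.892 to 0.998). Each of these genes fell in skin and changed the other way in epidermis. The average kept 1715 of the 3849 epidermis calls and 1685 of the 3718 skin calls in direction. With an array left out, counts ranged from 2793 to 3948 in epidermis, 2630 to 3822 in skin, 3110 to 3672 for the difference, 4026 to 5187 for skin against epidermis, 2269 to 3034 for the average, 4427 to 5162 for the average tissue contrast and 466 to 708 for genes changed alike in both tissues. The replicate block gave 3720, 3575, 3662, 4955, 2753, 5029 and 631 in the same order; of 18 correlations between same-number arrays of different groups 2 exceeded 0.1, so equal numbers were not taken as pairs. With probes lacking 1 gene the counts were 4744, 4429, 4634, 6125, 3416, 6320 and 753. A chip block was not run, since the column names give no chip. Signals close to background limit dim genes, and small changes fall below what 3 arrays detect.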

Other observations

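The tests below on averages over both tissues were chosen only after the result was seen. The T cell and Langerhans cell markers fell on average in 3 of 6 measured members and rose in 0, also adjusted over the list alone (median log2 −0.62, 6 arrays against 6, adjusted p = 0.020; adjusted p = 0.185 with an estimated correlation). The T cell receptor chain Cd3g was 2.09-fold lower on average, without passing in skin (−0.54, adjusted p = 0.209). In epidermis, where the mouse holds a resident population of dendritic T cells, Cd3e, Cd3d and Cd3g were 3.65-fold, 3.20-fold and 3.02-fold lower; Cd3e and Cd3d were detected on 1 of 3 Krt1-/- epidermis arrays. In skin Cd3e was undetected on all 3 Krt1-/- arrays and at least 1.62-fold lower, and Cd3d at least 1.41-fold lower. The Cd3d call in skin was lost without Krt1-/- skin replicate 2 (adjusted p = 0.0597) or Krt1+/+ skin replicate 3 (0.0683), and both calls were lost without background correction (0.057 for Cd3e, 0.0854 for Cd3d) and with the deposited normalized values (0.0504, 0.0771). A further probe of Cd3e was lower in skin without passing (−0.41, adjusted p = 0.156). The list did not pass in epidermis (1 rose and 4 fell, adjusted p = 0.131) or in skin (0 rose and 3 fell, adjusted p = 0.144) with camera, and passed in both with fry (0.0044 and 0.0144). Skint9, of a gene family expressed in thymus and epidermis, was 5.33-fold lower on average (adjusted p = 9.3e-04) and passed in both tissues. The class II antigen gene H2-Ab1 was 2.97-fold lower on average and passed in both tissues. H2-Aa, 2.92-fold lower on average, fell in epidermis but not in skin (−0.06), and the invariant chain gene Cd74, 2.39-fold lower on average, fell in skin but not in epidermis (−0.22), while the macrophage and dendritic cell list as a whole did not pass (1 rose and 2 fell of 14, adjusted p = 0.825).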
